A study of Mus musculus with 2 samples.

How the data were processed

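The study holds 2 one-colour microarrays of mouse liver, 1 for the PBS group and 1 for the TSG-6 group, each hybridised with the mixed RNA of 3 mice, per the labels' protocols and the series' design text. Cy3-labelled cRNA was made from 0.2 ug of RNA, per the labels. The deposited scanner files give the intensity of each spot on a linear scale as the software's processed signal, already background-subtracted and detrended within the array, per the file headers. The headers name Agilent Feature Extraction 11.5.1.1, while the submitters' processing notes name 10.7; the difference stays open. The deposited value table gives log2 values of the same arrays; set against the scanner files, each column equalled the log2 processed signal minus 1 constant within 0.001 for 99.7% of probes on both arrays, with a column median of -3.90 for PBS and -3.77 for TSG-6 and a 75th percentile near 0, so its scale and direction are known and no centring across arrays was found.

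The main values were log2 of the processed signal minus each array's 75th percentile over all non-control spots (a signal of 3158 on the PBS array and 2476 on the TSG-6 array). Control spots were left out, as were spots flagged as non-uniform or population outliers: 3.40% of non-control spots on the PBS array and 6.44% on the TSG-6 array. Flagged spots were bright, with a median signal of 5881 against 210.3 for all spots on the PBS array and 5421 against 178 on the TSG-6 array. The percentile was at one stage taken over spots without a flag; the choice of all non-control spots, which is the wording fixed before the data were examined, was settled after the counts of both had been seen, and the other is kept as an alternative. Leaving out flagged spots and calling a probe detected when at least 50% of its spots were well above background were also set after the data were seen. Flags removed every probe of 1253 genes, Arg1 among them.

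The files give a transcript accession for many probes and no gene name. Accessions, without version, were matched to symbols through a RefSeq gene table of assembly GRCm38.p6, used for names only; the array was designed on build mm9, per the file headers. Of 55681 non-control probes, 26762 matched a gene and 28919 did not. Of 20284 genes on the array, 15151 were measured on both arrays, 664 were well above background on 1 array and 3216 on none. Replicate spots were averaged, and a gene was read from the probe detected on the most arrays and then of highest mean signal. Of 175 genes past 2-fold with several measured probes, 154 had all probes on the same side of 0. For a gene above background on 1 array, the bright array's value was set against the higher of the dim probe's value and the lowest signal among detected probes (a log2 level of -7.04 on the PBS array and -7.06 on the TSG-6 array), as a lower bound.

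With 1 array per group there are no residual degrees of freedom, so genes were counted by a fixed size rule of 2-fold. For 36 gene lists and 18 cell type marker lists fixed before the data were examined, the median difference over measured members was set against 10000 random lists of the same size matched on mean expression in 20 bins; a list with at least 5 measured members was called when it lay outside the central 95%. Named genes followed a rule fixed at the same time: 10 genes of prior interest, the 10 highest and 10 lowest among genes at or above the median signal with the same sign in every alternative fixed beforehand, the 3 largest bounds in each direction among genes detected on 1 array, and up to 4 members of each list with the largest differences. By this rule, genes whose symbol is a clone, accession, Gm, Rik, LOC or lincRNA name were left out of the 10 highest and 10 lowest. They were left out of the bounds as well, which the rule did not state. Genes named outside the rule are said to be chosen after their values were seen. The rule takes 224 genes, of which the text names a part, and the others are not reported here.

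The steps were tested on simulated data for the same comparison, over 15151 genes with 200 changed: the size rule called 100% of genes changed 2.5-fold, 4-fold and 8-fold and 0% of those changed 1.5-fold, and 6 of 6 lists shifted by 0.4 and 0 of 4 unshifted lists were called. The simulation used the same spot noise at every signal level. Unchanged genes and list members had a spread of 0.3, drawn independently. The 200 changed genes had none, so their call rates reflect spot noise alone. On the real arrays the SD of differences ran from 0.26 to 0.81 over signal bins, and list members are regulated together. The simulation thus checks the steps and does not give their error rates on these arrays. Alternatives were normexp background correction with an offset of 50 (on the median spot signal and the median local background), quantile, median, loess and spike-in scaling, the percentile of detected probes, the deposited value table, no filter and a stricter filter on dim probes, the mean over a gene's probes, thresholds of 1.5-fold and 3-fold, and random lists without matching; 2 more, the percentile of unflagged spots and flagged spots kept, were chosen after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.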

Results

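Total liver RNA from male C57BL/6 mice with liver fibrosis was profiled after an intravenous dose of recombinant TSG-6, a secreted hyaluronan-binding protein encoded by Tnfaip6, or of PBS, its vehicle control. RNA was taken 2 weeks after treatment, and the RNA of 3 mice per group was mixed in equal parts. Each mixture was hybridised to 1 one-colour Agilent expression array, so that the study holds 2 arrays. The comparison asks how liver expression differed between fibrotic mice given TSG-6 and fibrotic mice given PBS. No liver without fibrosis was analysed here. Each array carried 59305 non-control spots. Of the spots used, 73.1% on the PBS array and 73.9% on the TSG-6 array were well above background, and none was saturated. With 1 pool per group there was no replicate, no test could be made and no p-value or SE is given. Every difference is that between these 2 pools. Array and group cannot be told apart, and the number of arrays limits the precision. All levels are log2 signals relative to the array's 75th percentile, and differences are the TSG-6 pool minus the PBS pool.

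Among 15151 genes measured on both arrays, 446 were at least 2-fold higher and 650 at least 2-fold lower in the TSG-6 pool, together 7.23% of the measured genes. Genes at or above the median signal were ranked, leaving out clone, accession, Gm, Rik, LOC and lincRNA symbols. The lowest in the TSG-6 pool was Sprr1a, a cornified envelope protein (30.1-fold lower). It was followed by the fatty acid elongase Elovl7 (12.7-fold lower), Afp, the fetal liver protein alpha-fetoprotein (12.1-fold lower), the stress transcription factor Atf3 (10.9-fold lower) and the inducible heat shock protein gene Hspa1a (8.31-fold lower). Akr1c18 (7.28-fold), Arhgap22 (6.36-fold), Tes (6.19-fold), Acta2 (5.55-fold) and the retinoic acid-producing enzyme Aldh1a2 (5.39-fold) completed the 10 lowest. On the higher side stood Cib3 (13.1-fold higher) and the neutrophil granule genes Ngp (12.7-fold), Ltf (11.2-fold) and Camp (6.87-fold). The other 6 of the 10 highest were the ammonium transporter Rhbg (8.75-fold), Cenpm (6.75-fold), the long noncoding RNA Meg3 (6.51-fold), the acetyl-CoA synthetase Acss2 (4.83-fold), Serpinb1a (4.27-fold) and the uridine phosphorylase Upp2 (4.13-fold). The probes of Acss2 and Meg3 differed among themselves, with log2 differences from 0.74 to 2.27 over the 2 probes of Acss2 and from 1.42 to 2.70 over the 3 of Meg3. Replicate spots of one probe gave a pooled SD of 0.13 for the log2 difference over 286 probes, a measure of spot noise that leaves out the spread between mice. Higher genes made up 40.7% of the genes past 2-fold, and this split depended on scaling. The share was 29.5% with the arrays scaled to their median, 29.0% after loess on the signal and 14.4% after scaling to the spike-in controls. It was 73.0% when the percentile was taken over spots without an outlier flag.

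**Figure D1:**
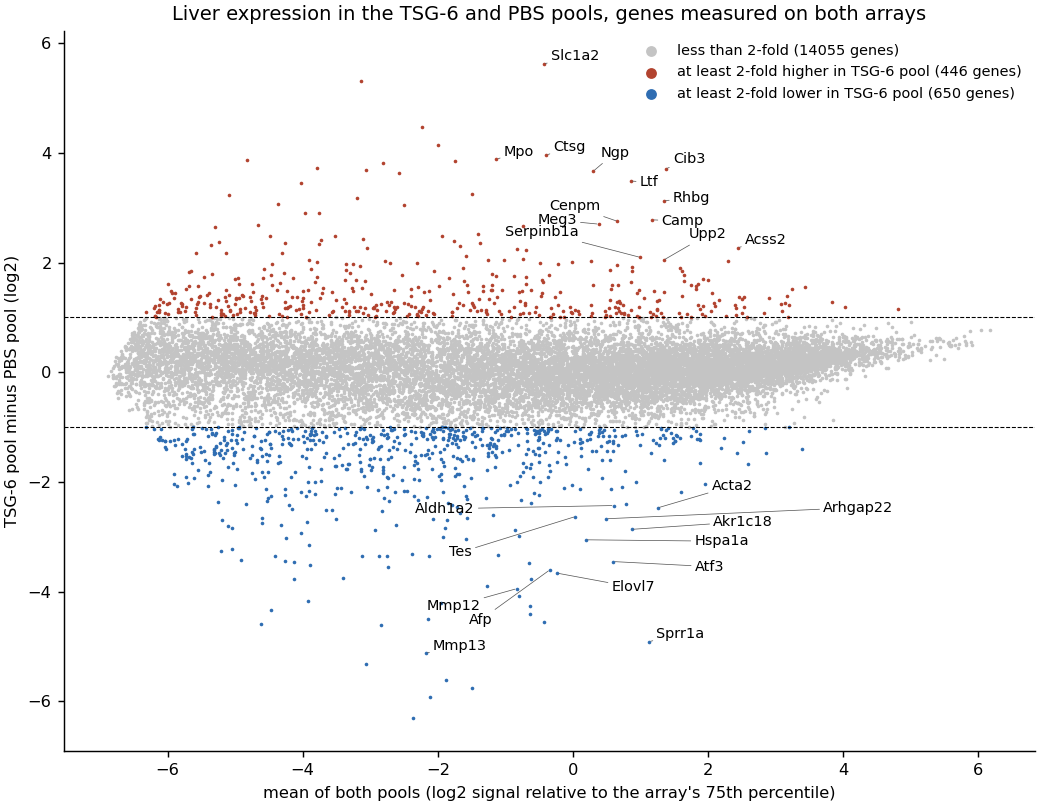
Difference between the TSG-6 and PBS pools (log2, vertical axis) against the mean of both pools (log2 signal relative to the 75th percentile, horizontal axis); each point is 1 of 15151 genes and dashed lines mark 2-fold. The 446 genes at least 2-fold higher are red and the 650 at least 2-fold lower are blue, with Slc1a2 and Cib3 among the highest and Sprr1a and Mmp13 among the lowest of the labelled genes.

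Genes of the fibrotic matrix and of activated stellate cells, the collagen-producing myofibroblasts of the injured liver, were lower in the TSG-6 pool. Of 22 measured markers of activated stellate cells, 6 were at least 2-fold lower and none was 2-fold higher. Their median log2 difference was -0.82, against -0.17 to 0.23 for the central 95% of random lists matched on expression. Acta2, which encodes the smooth muscle actin of myofibroblasts, was 5.55-fold lower, Cthrc1 3.75-fold, the collagen cross-linking enzyme Lox 3.11-fold and desmin (Des) 2.35-fold. Matrix remodelling enzymes and their inhibitors had a median of -0.78 with 8 of 25 at least 2-fold lower. They were led by the collagenase Mmp13 (34.8-fold lower), the macrophage elastase Mmp12 (15.4-fold) and Plau (3.99-fold); Timp1 was 1.95-fold lower. Under normexp background correction the log2 difference was -3.99 for Mmp13, -1.40 for Plau and -1.17 for Cthrc1, and the mean over the 2 probes of Lox was -1.04. Interstitial collagens had a median of -0.52, and 4 of 12 were at least 2-fold lower: Col15a1 (2.76-fold), Col8a1 (2.47-fold), Col5a1 (2.07-fold) and Col5a2 (2.03-fold). The 3 probes of Col15a1 ran from -1.46 to 0.04, and its difference was -0.51 under normexp. Col5a1 and Col5a2 were under 2-fold with the percentile of unflagged spots, at -0.76 and -0.73, and under normexp, at -0.96 and -0.91. The abundant fibrillar collagens differed less, with a log2 difference of -0.58 for Col1a1 and of -0.28 for Col3a1, the latter 0.01 with the percentile of unflagged spots. Other matrix glycoproteins lay below their random range (median -0.29, with Vcan 2.17-fold and Fbn1 1.92-fold lower), although the 2 measured probes of Vcan ran from -1.12 to -0.04. So did TGF-beta signalling genes (median -0.32, with Tgfb3 2.18-fold, Tgfb2 1.98-fold and Tgfb1 1.34-fold lower). Basement membrane genes (median -0.09, Nid1 1.66-fold lower with its brightest probe) and markers of portal fibroblasts and mesothelium (median -0.24, Eln 1.64-fold lower) lay within theirs. The 3 probes of Nid1 ran from -2.92 to -0.73, with a mean of -1.61.

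Quiescent stellate cell markers gave a median of 0.30, above the random range that ended at 0.27, and of -0.02 after spike-in scaling. The list lay inside the random range under normexp (percentile 95.3) and with flagged spots kept (91.8). Of 21 members 2 were at least 2-fold higher and 2 at least 2-fold lower. Hhip, an inhibitor of hedgehog signalling, was 5.10-fold higher and Hgf 2.36-fold lower. The 2 probes of Hhip ran from 1.21 to 2.35, and under normexp it differed by 1.72.

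The transcript of TSG-6 itself, Tnfaip6, differed by 0.22 with its brightest probe, and its 3 probes ran from -1.37 to 0.22. Under the alternative settings its difference ran from -0.80 to 0.50. The array measures RNA of the mouse gene, so its values do not report the injected protein. Cd44, the main hyaluronan receptor, differed by -0.09 with its brightest probe, its 4 probes running from -1.28 to -0.09 and its alternatives from -0.80 to 0.20. The list of genes for hyaluronan synthesis, binding and the inter-alpha-inhibitor had a median of 0.11 and a mean of -0.11 over 25 genes, inside the random range. The link protein gene Hapln1 was 2.63-fold lower, and -0.90 on the log2 scale under normexp. The hyaluronan synthase Has2, named after its value was seen, was well above background in the PBS pool only, at least 4.34-fold lower in the TSG-6 pool.

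Genes of recruited monocytes and macrophages were lower in the TSG-6 pool, with a median of -0.31 over 23 genes and 2 past 2-fold. Itgax, which encodes the integrin CD11c, was 2.70-fold lower and Gpnmb differed by -1.32 on the log2 scale, while Trem2, a receptor of lipid-associated macrophages, was 1.76-fold lower. Genes of alternative macrophage activation had a median of -0.36, with Egr2 3.74-fold and Chil4 2.60-fold lower and Socs2 3.58-fold higher. That list lay inside the random range with the stricter filter on dim probes (percentile 6.29). Arg1, also on that list, had only spots with an outlier flag and was 1.39-fold higher with them kept. Arg1 is on the urea cycle and periportal lists too, Socs2 on the growth hormone list and Egr2 on the immediate early list. In whole liver these genes do not report on macrophages alone. Kupffer cell markers, the resident macrophages, lay inside the random range (median 0.15, Timd4 2.39-fold higher). Inflammatory cytokines and NF-kB targets had a median of -0.11 at percentile 3.13 of random lists and so stayed inside the central 95%. Of them, 6 of 33 were at least 2-fold lower and 1 at least 2-fold higher. Lower were, among others, the chemokines Cxcl2 (3.85-fold, but -1.08 on the log2 scale under normexp), Ccl4 (3.54-fold) and Ccl7 (3.16-fold); Tnf was 1.95-fold lower. Vcam1 was 4.99-fold lower, yet -0.16 on the log2 scale with flagged spots kept. Classical macrophage activation (median -0.03) included Ccr7, 2.73-fold lower, and Il23a, 17.9-fold lower. Il23a was dim in the TSG-6 pool and differed by -2.81 on the log2 scale under normexp. Interferon-stimulated genes had a median of -0.15 over 35 genes, below the random range, and of 0.14 with the percentile of unflagged spots. Oas1g was 2.83-fold lower, and -0.69 on the log2 scale under normexp.

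Cell cycle genes had a median of -0.60, with 8 of 42 at least 2-fold lower and none 2-fold higher. Ccne1, the cyclin of the G1/S transition, was 6.04-fold lower, the replication licensing factor Cdc6 4.49-fold, and the replicative helicase subunits Mcm2 and Mcm5 3.35-fold and 3.09-fold. Immediate early genes had a median of -0.64, with 10 of 30 at least 2-fold lower, including Atf3 (10.9-fold), Ier3 (4.72-fold), Egr2 (3.74-fold) and Dusp5 (3.61-fold). In the list of unfolded protein and heat shock genes 11 of 32 were at least 2-fold lower, among them Hspa1a (8.31-fold), Hyou1 (3.75-fold) and Hsph1 (3.48-fold); the median of that list, -0.24, was 0.05 with the percentile of unflagged spots. Under normexp the log2 difference was -0.74 for Dusp5 and -0.90 for Hyou1, both under 2-fold. Genes of the p53 response had a median of -0.25 (0.04 with the percentile of unflagged spots, and percentile 3.07 with the stricter filter), with Phlda3 2.70-fold and Cdkn1a 1.95-fold lower.

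Neutrophil genes had a median of 0.91 over 22 genes, of which 10 were at least 2-fold higher and 1 at least 2-fold lower in the TSG-6 pool; 4 lay below 0. The genes of granule proteins led: the serine protease Ctsg was 15.6-fold higher, myeloperoxidase (Mpo) 14.8-fold, Ngp 12.7-fold and lactoferrin (Ltf) 11.2-fold. Genes of mature neutrophils on the same list, named here after their values were seen, differed less: S100a9 by 0.18, Csf3r by 0.44 and the chemokine receptor Cxcr2 by -0.19. Markers of mast cells, basophils and eosinophils had a median of 0.38, with Mcpt8 8.44-fold (1.74 on the log2 scale under normexp) and Prg2 2.77-fold higher and Siglecf 3.04-fold lower. This list lay inside the random range under normexp, with no filter on dim probes and with flagged spots kept. Red cell and erythroid markers had a median of -0.02 and a mean of 0.43 over 12 genes, with Car1 5.14-fold and the erythroid transcription factor Klf1 4.01-fold higher. The alpha-globin gene Hba-a1, named after its value was seen, differed by -0.13. Markers of T and NK cells (median -0.07), B and plasma cells (0.04, mean -0.14), dendritic cells (-0.02) and platelets (0.32) were within their random ranges. Derl3, a plasma cell marker that is also part of protein degradation in the endoplasmic reticulum, was 21.2-fold lower. MHC class II genes (0.23) were also within range.

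**Figure D2:**
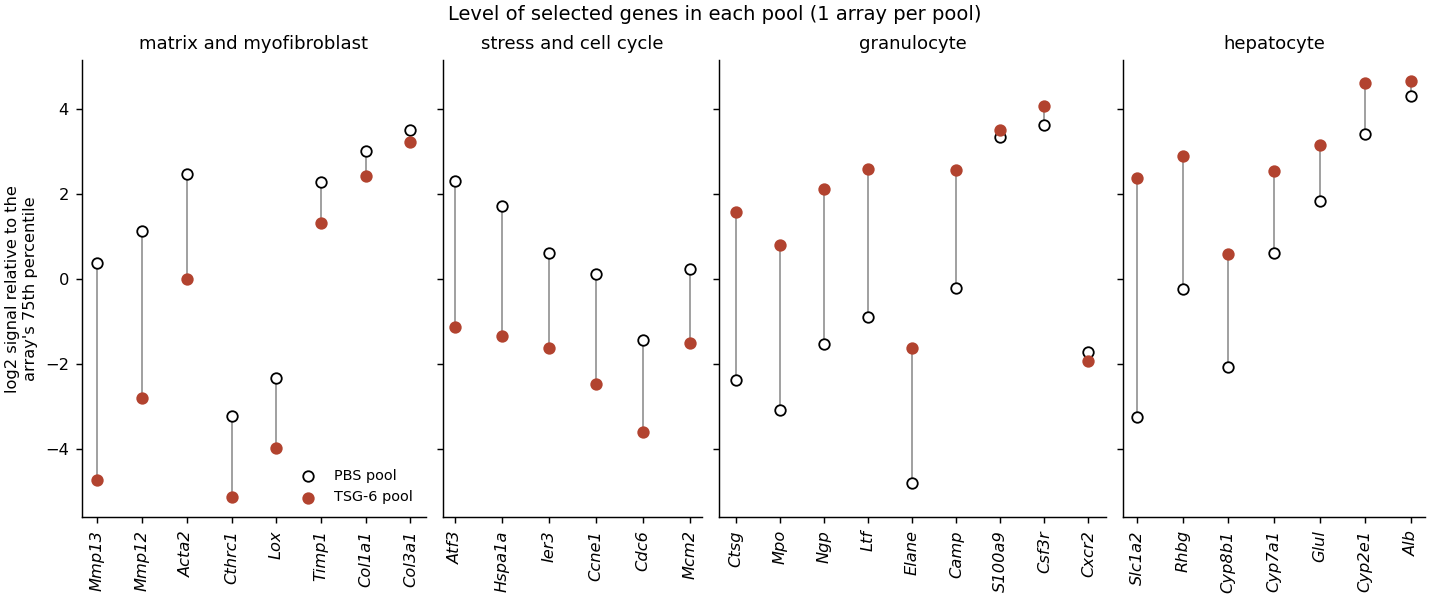
Level of selected genes (log2 signal relative to the array's 75th percentile) in the PBS pool (open circles) and the TSG-6 pool (red), 1 array each, joined by a line per gene; there are no error bars because there is 1 pool per group. Matrix, stress and cell cycle genes lie lower and granule genes such as Mpo lie higher in the TSG-6 pool, while S100a9, Csf3r and Cxcr2 lie within 0.44 of the PBS pool.

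Hepatocyte metabolism genes were higher in the TSG-6 pool, among them those of the pericentral zone, the hepatocytes around the central vein. Of 28 pericentral genes, 11 were at least 2-fold higher and none 2-fold lower, with a median of 0.79 against a random range of 0.08 to 0.31. The glutamate transporter Slc1a2 was 49.3-fold higher with its brighter probe, but its 2 probes ran from 1.17 to 5.62 on the log2 scale. Rhbg was 8.75-fold higher, Cyp7a1, the rate-limiting enzyme of bile acid synthesis, 3.76-fold, glutamine synthetase (Glul) 2.51-fold and Cyp2e1 2.27-fold. Periportal genes, of the opposite zone, had a median of 0.40 within their random range of 0.17 to 0.40, at percentile 96.5, and no member passed 2-fold. They lay above the range in 4 alternatives: quantile normalization (percentile 99.9), loess (99.8), the mean over a gene's probes (97.8) and unmatched random lists (99.8). Drug-metabolising cytochromes P450 had a median of 0.76, with 8 of 23 at least 2-fold higher, among them Cyp2b13 (3.25-fold), Cyp2c37 (2.62-fold), Cyp2c50 (2.43-fold) and Cyp2c54 (2.33-fold); members of these families have similar sequences, so the values of single members are uncertain. Amino acid and urea cycle enzymes had a median of 0.54, with Prodh 2.38-fold, Bhmt 2.24-fold and Oat 2.06-fold higher. The 3 probes of Bhmt ran from 0.32 to 1.16. Bile acid genes had a median of 0.43. Cyp8b1, the sterol 12-alpha-hydroxylase, was 6.34-fold higher, the basolateral transporter subunit Slc51b 4.18-fold and Cyp27a1 2.79-fold, while the export pump Abcc4 was 2.42-fold lower. Cholesterol synthesis genes (0.44, Dhcr7 2.15-fold higher) lay above their random range. Fatty acid synthesis and triglyceride storage (0.44, Acacb 4.08-fold higher and Cidea 3.29-fold lower) and fatty acid oxidation with PPAR-alpha targets (0.35, Pdk4 2.21-fold higher, the hormone Fgf21 2.68-fold lower) also lay above their random ranges. Several of the higher genes were under 2-fold after spike-in scaling. Their log2 differences were then 0.96 for Cyp2c50, 0.93 for Prodh, 0.90 for Cyp2c54 and 0.86 for Cyp2e1. Those of Bhmt, Pdk4, Dhcr7 and Oat were 0.84, 0.82, 0.78 and 0.72.

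The list of female-biased liver genes and the list of growth hormone and male-biased genes were both higher, in male mice on both arrays. Female-biased genes had a median of 0.81 with 8 of 19 at least 2-fold higher, led by the sulfotransferase Sult3a1 (17.7-fold), the transcription factor Cux2 (3.91-fold) and Fmo2 (3.37-fold). Growth hormone and male-biased genes had a median of 0.44 with 6 of 22 at least 2-fold higher. This list mixes growth hormone targets, such as Cish and Socs2, with male-biased genes, so it does not show a rise of male-biased genes as such. The growth hormone target Cish was 3.61-fold higher and Hsd3b5 5.64-fold lower (-1.52 on the log2 scale under normexp). Cyp4a12a was 5.39-fold higher, an uncertain value since Cyp4a12a and Cyp4a12b are near-identical. Albumin (Alb) was 1.29-fold higher, and 0.01 below the PBS pool on the log2 scale under the alternative at the low end. Secreted hepatocyte proteins (median 0.36, Serpina7 4.56-fold lower and Serpina6 2.40-fold higher), and acute phase proteins (0.29, Hamp2 2.85-fold higher) were within their random ranges. So were gluconeogenesis and glucose metabolism (0.25, Irs2 higher by 1.32 on the log2 scale), liver-enriched transcription factors (0.22, Onecut1 3.99-fold higher) and NRF2 and glutathione genes (0.27, Nqo1 2.18-fold higher). Wnt and YAP targets (0.15, Sp5 4.96-fold higher) and circadian clock genes (0.04, mean -0.02, Per2 4.25-fold lower) were within their random ranges. Past 2-fold, 3 of 22 Wnt and YAP targets were higher and 3 lower, and 1 of 26 acute phase genes was higher and 2 lower. Of 20 circadian genes 1 was higher and 2 lower, and of 25 NRF2 and glutathione genes 1 was higher and 1 lower.

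**Figure D3:**
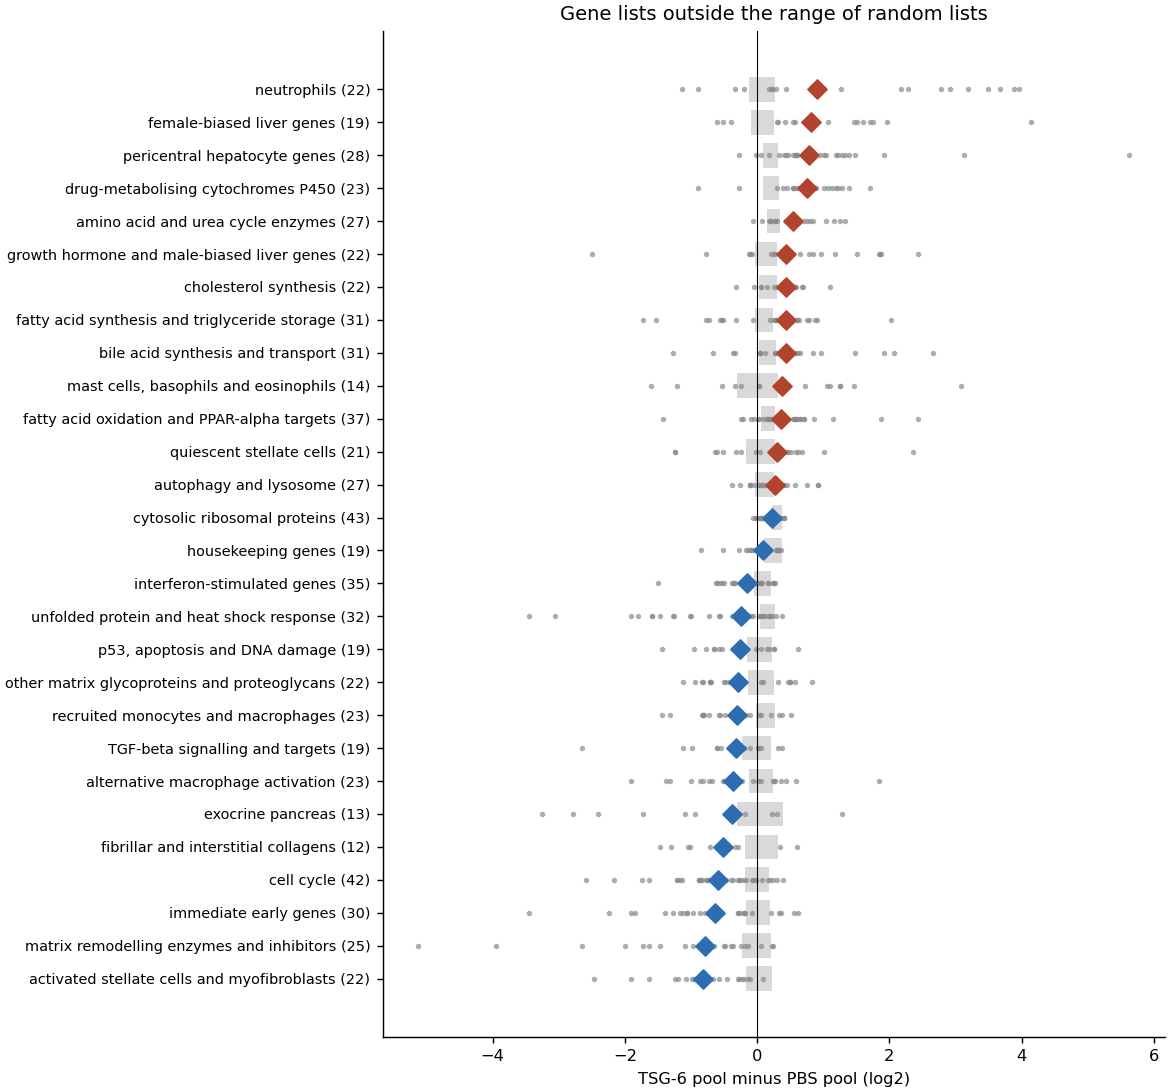
Log2 difference between the TSG-6 and PBS pools (horizontal axis) for the 28 gene lists outside the central 95% of random lists; grey dots are measured members (their number in parentheses), diamonds are list medians, and grey bars span the central 95% of 10000 random lists matched on expression. Medians run from -0.82 for activated stellate cells to 0.91 for neutrophils, and 7 of the 28 change sign under some scaling.

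Of the 54 lists tested, 13 lay above and 15 below the central 95% of their random lists, where chance alone would place 2.7. Members of a list are regulated together, so this is a description of the 2 pools and not a test. Lists also share members, such as Cyp2e1 on the cytochrome P450 and pericentral lists and Glul on the pericentral and amino acid lists. The called lists are therefore not separate results. Of the 26 other lists, the medians of 23 changed sign under some scaling, and 13 lay inside the random range in every alternative. Autophagy and lysosome genes were above their range (median 0.28, Atg14 1.89-fold higher; -0.05 after spike-in scaling). They lay inside it under normexp (percentile 94.8), loess (96.8) and with flagged spots kept (77.4). Cytosolic ribosomal proteins (0.23) and housekeeping genes (0.09) were called lower only against random lists of equally bright genes, whose medians were higher still, and both medians turned negative after quantile, loess and spike-in scaling. Without matching, ribosomal proteins lay above the range (percentile 98.3) and housekeeping genes inside it (52.5). Oxidative phosphorylation genes (0.22) were within range. Endothelial markers (0.10, Dnase1l3 1.78-fold higher) and cholangiocyte markers (-0.06, Tff3 2.24-fold lower) lay within range. For tissues next to the liver, exocrine pancreas genes were lower in the TSG-6 pool, with a median of -0.39 over 13 genes, of which 5 were at least 2-fold lower and 1 at least 2-fold higher. Lower were Prss2 (9.55-fold), Try5 (6.91-fold), Ctrb1 (5.30-fold) and Cela1 (3.30-fold). Under normexp the log2 difference was -1.44 for Prss2, -1.57 for Try5 and -1.19 for Ctrb1. With 6 further genes above background in 1 pool only set at their bounds, that median was -1.09. Skeletal muscle (-0.11, Acta1 at -1.59), gut and gallbladder epithelium (0.05, mean -0.37, Krt20 2.87-fold lower) and adipose markers (0.28, Car3 1.81-fold higher) were within range.

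A further 664 genes were well above background in 1 pool only. Counted against the detection floor, 57 of them were at least 2-fold higher and 95 at least 2-fold lower in the TSG-6 pool. The largest bounds are given for genes without a clone, accession, Gm, Rik, LOC or lincRNA symbol. On the lower side they were Mrgprf (at least 728-fold), Sprr1b, a relative of Sprr1a (at least 141-fold), and Uts2 (at least 64.0-fold), each from 1 probe. On the higher side they were Prok2, a chemokine-like protein (at least 7.82-fold), Tctex1d1 (at least 6.01-fold) and Olfr728 (at least 5.98-fold).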

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

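Probes that could not be matched to a gene entered no comparison of the report, and with the main scaling more of them were higher than lower in the TSG-6 pool against the PBS control pool. Of 17219 such probes measured on both arrays, 690 were at least 2-fold higher and 330 at least 2-fold lower in the TSG-6 pool, with a median log2 difference of 0.23 against 0.08 for the measured genes. Among the 9672 of them that are named by a chromosome region, 361 were at least 2-fold higher and 167 at least 2-fold lower. This split follows the scaling, by alternatives chosen after seeing the data. Of all such probes past 2-fold 67.6% were higher, against 51.7% under quantile, 50.9% under median, 45.3% under loess and 25.6% under spike-in scaling and 91.7% with the percentile of unflagged spots. After spike-in scaling the counts were 265 higher and 769 lower (126 and 436 for region probes), and the median was -0.09. The 2 region probes furthest up, at a mean signal at or above the median of region probes, were A_30_P01032927 on chromosome 3 (121615836 to 121616109, build mm9), 12.6-fold higher, and A_30_P01030934 on chromosome 2 (67836003 to 67836461), 7.61-fold higher. The 2 furthest down were A_30_P01027936 on chromosome 12 (73838608 to 73862621), 376-fold lower, and A_30_P01027732 on chromosome 1 (115829055 to 115854155), 46.1-fold lower. Each is a difference between 2 single arrays, and no explanation was tested.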

How the results depend on the processing

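The alternatives over unflagged spots and with flagged spots kept, and the scalings of probes without a gene, were chosen after seeing the data; all others were planned. No paired analysis was possible because each group holds 1 array, and no replicate could be left out. Relative to the main scaling, the median of all measured genes moved by -0.10 under quantile, -0.11 under median, -0.13 under loess and -0.32 under spike-in scaling and by 0.29 with the percentile of unflagged spots, so counts by direction follow the scaling by construction. Of the 28 called lists, 21 kept their call in each of the 8 alternatives that could change it and gave a value; 5 others move all genes by 1 constant, which leaves list percentiles as they are. The medians of 21 kept their sign in every scaling.

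The counts past 2-fold, 446 higher and 650 lower, were 290 and 402 under normexp, 212 and 1257 under spike-in scaling, 1018 and 376 with the percentile of unflagged spots, and 128 and 117 with the stricter filter on dim probes; without a filter 907 were higher. At 1.5-fold they were 1591 and 1567, and at 3-fold 125 and 225. Of the genes past 2-fold, spike-in scaling shared 212 higher and 650 lower genes with the main setting, and the percentile of unflagged spots 446 and 376. The bounds past 2-fold for genes detected in 1 pool, 57 for TSG-6 and 95 for PBS, were 5 and 21 under normexp and 132 and 62 with unflagged spots, and the TSG-6 count was 29 under quantile, 32 under loess and 22 under spike-in scaling.

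Percentiles among random lists crossed the central 95% as follows, and the cause was not tested unless the alternative changes which genes or random lists enter. Under normexp, autophagy (94.8), quiescent stellate cells (95.3) and mast cells, basophils and eosinophils (79.3) fell inside, and portal fibroblasts (2.49), cholangiocytes (1.66) and platelets (99.1) moved outside. Under quantile normalization, NRF2 and glutathione (99.4), liver transcription factors (98.7), periportal genes (99.9), cholangiocytes (1.56) and platelets (98.5) moved outside. Loess left autophagy inside (96.8) and put periportal genes (99.8) and platelets (98.3) outside. Without a filter on dim probes, inflammatory genes (1.90) and secreted hepatocyte proteins (98.7) moved outside, and ribosomal proteins (5.39), housekeeping genes (3.54) and the mast cell list (71.9) inside. With the stricter filter, alternative macrophage activation (6.29) and p53 genes (3.07) fell inside, and Wnt and YAP targets (99.04), cholangiocytes (0.52) and skeletal muscle (0.39) outside. With the mean over a gene's probes, NRF2 (99.6), secreted proteins (99.2), transcription factors (99.7), periportal genes (97.8), portal fibroblasts (2.25) and platelets (99.6) moved outside. With flagged spots kept, basement membrane (0.165), inflammatory genes (2.16) and NRF2 (98.2) moved outside, and autophagy (77.4), housekeeping genes (3.77), quiescent stellate cells (91.8) and the mast cell list (95.6) inside. Against unmatched random lists, ribosomal proteins turned from below to above (98.3), housekeeping genes fell inside (52.5), and inflammatory genes (2.35), acute phase (99.1), NRF2 (98.0), secreted proteins (99.98), periportal genes (99.8), oxidative phosphorylation (97.55), portal fibroblasts (0.98) and platelets (97.9) moved outside. Signal over background limits the dim genes, since 3216 genes were above background on neither array. The SD of differences was 0.26 in the brightest of 10 signal bins, 0.81 in the fourth dimmest and 0.60 in the dimmest. It thus did not rise steadily towards the dim genes.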

Other observations

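The tests of the precursor genes and of loess were written before their results were seen; those of blood, mature neutrophils, spot noise, rapid immediate early genes and the hepatocyte share were chosen after.

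Genes of granule proteins (Mpo, Ctsg, Elane, Prtn3, Ltf, Ngp and Camp) had a median log2 difference of 3.49 in favour of the TSG-6 pool; more blood there would also raise globin transcripts, but Hba-a1 and Hba-a2 differed by -0.23 on average. Mature neutrophil genes (Cxcr2, Csf3r, Mmp9, S100a9, Trem1 and Il1r2) had a median of 0.20 and ran from -0.89 to 0.44, so these genes did not share the rise. They were picked after values had been seen, and 10 of 22 genes of the neutrophil list were at least 2-fold higher. The set therefore does not decide whether mature cells rose. Noise of single spots is argued against, since the neutrophil list and a list of granulocyte precursor genes, both chosen without their values, lay at percentile 100 of random lists, whose genes carry the same noise. For early granulocyte precursors, 9 measured genes of an 11-gene list gave a median of 0.97, short of the value of 1 set beforehand but above the random range, which ended at 0.39; Ms4a3 was 22.3-fold, Itgb2l 10.9-fold and Fcnb 5.63-fold higher, while Gfi1 differed by 0.41. Granulocyte precursors in the livers of the TSG-6 pool, or in 1 of its 3 mice, may be the source, and a pool cannot show which. Of 12 red cell and erythroid markers, 3 were also at least 2-fold higher, with Car1 at 2.36 and Klf1 at 2.01, while 7 lay below 0. Whether the source was granulocyte precursors alone was not tested.

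Immediate early and stress genes were lower in the TSG-6 pool. To look at a scaling trend with signal, loess was applied, and the percentile of both lists was then 0. Random lists matched on expression share such a trend, so these percentiles could hardly move and do not decide. The medians, -0.64 for immediate early and -0.24 for stress genes before loess, were -0.71 and -0.47 after it. Taking out the fitted trend thus did not remove the difference. A delay in handling the PBS livers could raise rapid immediate early genes there: 7 of 9 were lower in the TSG-6 pool, Fosb by -1.40 and Fos by -1.07, but Egr1 was 0.56 and Zfp36 0.22 higher, so neither of the outcomes set for this test was met. Handling and treatment cannot be told apart with 1 pool per group, and an effect of TSG-6 stays open and untested.

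Hepatocyte metabolism genes were higher and myofibroblast genes lower in the TSG-6 pool. A higher share of hepatocytes would lower the markers of the other cell types alike. Of 13 marker lists, 2 lay below their random range, 3 above and 8 inside. Of the 2 below, 1 was the activated stellate cell list, itself part of this pattern. The rule for this tally was set after seeing the data, so it does not decide how far a higher share contributed. The tally moved with the setting: 4 lay below and 2 above under normexp, which had the most below of the alternatives, and 2 below and 1 above with flagged spots kept. After loess, 3 of 3 lists (cytochromes P450, pericentral genes and activated stellate cells) stayed outside their random ranges on the same side, with medians of 0.60, 0.59 and -0.91. Random lists matched on expression share a trend with signal, so loess could hardly move these calls, and the first 2 lists share members. A difference of zonal and fibrogenic expression between the groups is a hypothesis that remains open and was not tested. The periportal list also had a positive median, of 0.40.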
